A study of Arabidopsis thaliana with 12 samples.

How the data were processed

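The series measured genomic DNA of sorted leaf nuclei of Arabidopsis thaliana, strain Columbia, by Illumina sequencing, in wild type and in the atxr5 atxr6 double mutant. Per the labels, nuclei of the ploidy classes 2C, 4C, 8C and 16C gave 1 library per genotype and class, so 8 sorted libraries. A further 4 libraries were an input of each genotype, a chromatin immunoprecipitation (ChIP) of histone H3 monomethylated at lysine 27 (H3K27me1) from wild type, and a ChIP of histone H3 from atxr5 atxr6. Per the labels' protocols, DNA of the sorted nuclei was extracted with the PicoPure kit, and libraries followed the Illumina instructions.

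Each deposited file held 1 line per aligned read, with a chromosome, a strand and a position, and no header and no sequence. The aligner, the genome build and the filters were not given in the sources used here. Coordinates are therefore those of the files, counted from 1, with the build not named. The highest read position was 30432522 on chromosome 1, 19705074 on chromosome 2, 23470770 on chromosome 3, 18585008 on chromosome 4 and 26992695 on chromosome 5. In 9 of the 12 deposited files, the 8 sorted libraries and the H3 ChIP, no combination of start and strand occurred more than once. The other 3 held repeats, which made up 7.41% of the lines of the wild-type input, 5.49% of the mutant input and 26.9% of the H3K27me1 ChIP, with up to 401, 411 and 569 reads at one start and strand. Sorted libraries were compared with sorted libraries for this reason, and values that use an input were also computed with each start and strand counted once. A library with each start kept once saturates where reads are dense, so each 10 kb bin was also corrected for starts on occupied positions, an alternative chosen after the data were examined. The median correction in the 16C mutant library was 1.03-fold.

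Reads were counted per region and in 10 kb bins with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Exact intervals and rank correlations came from scipy 1.17.1, and plots from matplotlib 3.10.9. The pericentromeres, fixed before the data were examined, were 12 to 18 Mb of chromosome 1, 1 to 7 Mb of chromosome 2, 11 to 17 Mb of chromosome 3, 1 to 6 Mb of chromosome 4 and 9 to 15 Mb of chromosome 5, 29 Mb in all. The rest of the 5 nuclear chromosomes is called the arms. A share of reads carries an exact Clopper-Pearson interval at the 95% level. A mutant over wild-type ratio is the ratio of reads in a region over reads in the arms, mutant divided by wild type, with an exact conditional binomial interval of the region's reads that takes the arm totals as fixed. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only, and they compare 2 libraries, not 2 conditions.

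With 1 library per genotype and ploidy class there is no replicate check, and no p-value was computed across bins. A 10 kb bin was called higher where the mutant over wild-type ratio of reads, scaled to the median tested bin, was 1.5 or more, and lower at the inverse of 1.5 or less, in bins with at least 50 wild-type reads. The same rule was run on the 6 pairs of wild-type sorted libraries as the background. Bins called at 16C were then measured in the 2C, 4C, 8C and input pairs, which had not been used to choose them. Called bins that were adjacent or 1 bin apart were merged into regions. The regions named are the 10 longest, with ties going to the higher ratio. The rule also provided for the 5 lowest bins among those lower at both 16C and 8C, of which there were 0. The only test across libraries was a two-sided exact permutation test of the mean log2 ratio, in which the genotype was swapped within each ploidy class. Its 16 arrangements allow no p below 0.125.

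The calling step was tested on simulated read counts for the 16C pair, with 200 bins changed by a known fold. At a true fold of 1.5, on the threshold, it called 85 of the 200, or 42.5%, among 11806 tested bins. It called all 200 at 2-fold and all 200 at 3-fold, among 11802 tested bins each. At most 1 unchanged bin was called at any fold.

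H3K27me1 ChIP reads were divided by wild-type input reads, and H3 ChIP reads by mutant input reads, per 10 kb bin and scaled to the median tested bin. The 2 ChIP libraries differ in both antibody and genotype, so they were not set against each other. The classes of H3K27me1 over input used each start and strand once and left out 3.2 to 3.5 Mb of chromosome 2. These classes, the first 0.1 Mb of chromosomes 2 and 4, and the interval at 3.2 to 3.5 Mb of chromosome 2 were chosen after the data were examined. So was the end of each chromosome, taken from 2 Mb before its last whole Mb onward and thus longer than 2 Mb.

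Alternatives planned before the data were examined were other limits of the pericentromeres, each start and strand once, bins with extreme input left out, another reference library, other ratios, bin sizes (bins of 1 kb with at least 10 wild-type reads), scalings and read minimums, permutation without the ploidy block, and ploidy classes left out in turn. Alternatives chosen afterwards were bins of 1 kb with at least 50 wild-type reads, the interval of chromosome 2 left out, the correction for occupied positions, and the input as reference with each start and strand once. The gene table supplied for this work, of assembly TAIR10.1, was not used. The build of the files is not named, and their highest read positions run past the chromosome lengths expected for that assembly. For that reason the gene and transposon contents of the regions, the fixed gene lists, the insertion sites in the mutant genes and a correction for GC content were not analysed here.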

Results

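Leaf nuclei of Arabidopsis thaliana go through endoreduplication, in which DNA is replicated without cell division, so that one leaf holds nuclei of 2C, 4C, 8C and 16C DNA content. ATXR5 and ATXR6 are histone methyltransferases that add a single methyl group to lysine 27 of histone H3. The series allows genomic DNA content in such nuclei to be compared between wild type and the atxr5 atxr6 double mutant. It comprised 12 libraries, with 1 per genotype and ploidy class, 1 input per genotype, an H3K27me1 ChIP from wild type and an H3 ChIP from atxr5 atxr6. The wild-type sorted libraries held 9850259 nuclear reads at 2C, 9003004 at 4C, 9495334 at 8C and 9926198 at 16C. Their mutant counterparts held 14184154, 8162335, 12093644 and 12183611 nuclear reads. The inputs held 8504511 reads in wild type and 6863293 in the mutant, the H3K27me1 ChIP 1734436 and the H3 ChIP 688083. There were no replicate libraries, and every interval below is a 95% interval of counting error that compares the libraries named.

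Pericentromeric DNA took a larger share of the reads in atxr5 atxr6 than in wild type, and the gap widened from 2C to 8C. In wild type the share was 20.8% at 2C, 20.5% at 4C, 20.6% at 8C and 20.7% at 16C. In atxr5 atxr6 it was 21.5% at 2C, 22.9% at 4C, 26.8% at 8C and 27.0% at 16C, and the widest exact interval of the 8, at mutant 4C, ran from 22.90% to 22.96%. Relative to the arms, the mutant held 1.04 times as many pericentromeric reads as wild type at 2C (interval 1.036 to 1.040), 1.15 times at 4C (1.149 to 1.154), 1.41 times at 8C (1.406 to 1.411) and 1.42 times at 16C (1.416 to 1.421). In the unsorted inputs the ratio was 1.06 (1.058 to 1.062).

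**Figure D1:**
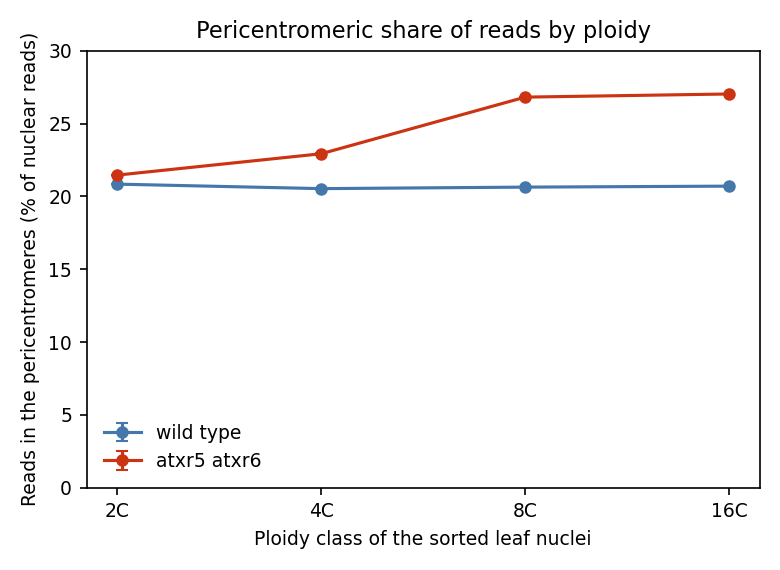
Share of nuclear reads in the pericentromeres (y axis, percent) against the ploidy class of the sorted nuclei (x axis), 1 library per point, with exact 95% intervals smaller than the symbols. Wild type stays between 20.5% and 20.8%, while atxr5 atxr6 goes from 21.5% at 2C to 27.0% at 16C.

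Every chromosome took part in the 16C difference. The mutant over wild-type ratio was 1.30 in the pericentromere of chromosome 1 (1.295 to 1.306), 1.48 on chromosome 2 (1.472 to 1.483), 1.42 on chromosome 3 (1.418 to 1.428), 1.47 on chromosome 4 (1.463 to 1.475) and 1.41 on chromosome 5 (1.406 to 1.417). At 8C the values were 1.30, 1.41, 1.43, 1.47 and 1.43 in the same order. The interval from 3.2 to 3.5 Mb of chromosome 2 stood at 1.86 at 16C and 1.27 at 8C. Without it, the pericentromere of chromosome 2 stood at 1.43 at 16C and 1.42 at 8C. The heterochromatic knob on the short arm of chromosome 4, taken as 1.6 to 2.3 Mb, stood at 1.03 at 2C, 1.15 at 4C, 1.51 at 8C and 1.48 at 16C (1.460 to 1.493). The ends of the 5 chromosomes, each taken from 2 Mb before its last whole Mb onward, lay between 0.955 and 0.989 at 16C relative to all arm sequence. At the other end of chromosomes 2 and 4, outside the fixed pericentromeres, the first 0.1 Mb stood at 1.81 and 1.57.

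**Figure D2:**
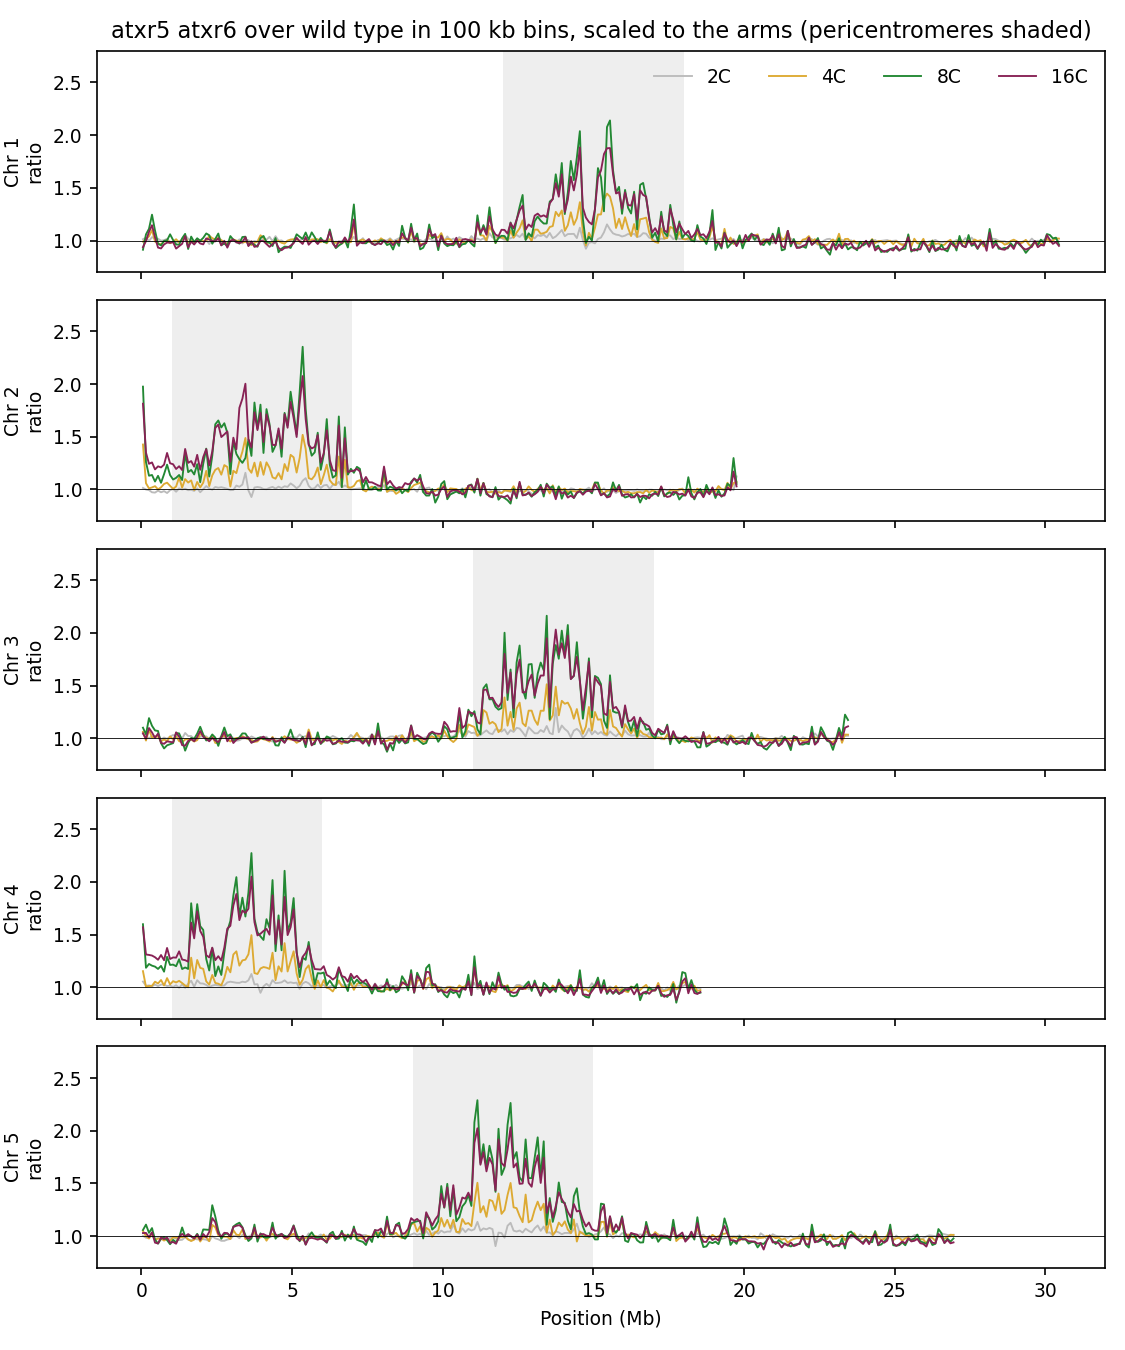
Ratio of atxr5 atxr6 to wild-type reads (y axis, linear, scaled to the arms) in 100 kb bins along the 5 chromosomes (x axis, Mb), with 1 line per ploidy class and the pericentromeres shaded. The 8C and 16C lines rise over the shaded pericentromeres, where the summed ratios are 1.41 and 1.42, while the 2C line stays near its summed ratio of 1.04.

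Over the 4 ploidy classes the mean log2 ratio of mutant to wild type was 0.31 (SD 0.22, n = 4 pairs), with the mutant higher in 4 of 4 pairs. A two-sided exact permutation test that swapped the genotype within each class gave p = 0.125, the smallest value that 16 arrangements allow, so this test could not pass 0.05. Permuted without the ploidy block, the same 8 libraries gave an exact permutation p of 0.0286, the smallest that 70 splits allow. The classes are not replicates of each other, and their SD includes the trend with ploidy.

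Within each genotype, the sorted libraries were compared with the 2C library to ask whether pericentromeric DNA kept pace with the arms as ploidy went up. In wild type the pericentromere over arm ratio relative to 2C was 0.981 at 4C (0.979 to 0.983), 0.988 at 8C (0.986 to 0.990) and 0.992 at 16C (0.990 to 0.994). In atxr5 atxr6 it was 1.09 at 4C (1.087 to 1.091), 1.34 at 8C (1.339 to 1.343) and 1.36 at 16C (1.354 to 1.358). The unsorted mutant input lay at 1.16 relative to the mutant 2C library. The wild-type input lay at 1.14 relative to wild-type 2C. Both inputs held repeated starts, which the 2C libraries did not. With each start and strand once, the pericentromere over arm ratio of the wild-type input fell from 0.300 to 0.267, against 0.263 at 2C. That of the mutant input fell from 0.318 to 0.284, against 0.273 at 2C. Most of the offset thus went with the repeated starts in both genotypes, and what remained was larger in the mutant. With the mutant input as the reference in place of 2C, mutant 4C over input was 0.937, below 1 because the input lay above 4C relative to 2C. That input held repeated starts, and with each start and strand once the value was 1.05.

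At the scale of 10 kb, 837 of 11801 tested bins were higher in the 16C mutant library by the 1.5-fold rule and 0 were lower. Pericentromeres held 735 of the 837, or 87.8%, against 23.8% of the tested bins. The remaining 102 lay in the arms. Put differently, 26.2% of the tested pericentromeric bins were called and 1.13% of the arm bins. By chromosome, 124 called bins lay on chromosome 1, 188 on chromosome 2, 175 on chromosome 3, 170 on chromosome 4 and 180 on chromosome 5. The highest ratio of a bin was 3.26. The absence of lower bins depended on the setting, as a threshold of 25% gave 1842 higher and 97 lower bins, and bins of 1 kb with at least 10 wild-type reads gave 9034 higher and 2873 lower. With at least 50 reads, as in the main rule, bins of 1 kb gave 6904 higher and 2424 lower. No background from wild-type pairs is given for these settings. Bins of 1 kb hold fewer reads, so counting error alone carries more of them past a threshold. Their lower bins are not shown to be losses.

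The same rule called 973 higher bins at 8C, 759 of them pericentromeric, 345 at 4C and 0 at 2C. A single bin was lower at 8C, chromosome 1 from 27040001 to 27050000, at 0.628, and it is named after its value was seen. The input pair gave 11 higher and 2 lower bins. The 2 lower ones, also named after their values were seen, were chromosome 2 from 2550001 to 2560000 at 0.632 and chromosome 3 from 7850001 to 7860000 at 0.622. As the background, the 6 pairs of wild-type libraries gave 0 higher bins each, except 1 in the pair of 16C and 8C (chromosome 1, 14390001 to 14400000, 1.64), and 0 to 4 lower bins. Those lower bins had 54 to 99 reads in the reference library, except chromosome 3 from 13540001 to 13550000, which had 2164 at 2C and a ratio of 0.613 at 16C.

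Most of the bins called at 16C were called at 8C too, from separate libraries of both genotypes. Of the 837, 765 were shared, where lists of these sizes drawn independently from all 11800 bins tested in both would share 69.0. Both lists lay mostly in the pericentromeres, which alone raises the expected overlap, so 69.0 is too low as a chance level. In the arms 101 of the 102 were shared. The 4C list was smaller, and 336 of its 345 bins were in the 16C list. Lists drawn from all tested bins would share 24.5, which is too low for the same reason.

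Measured in the pairs that did not choose them, the bins called at 16C held 1.096 times as many reads in the mutant as in wild type at 2C (1.0927 to 1.0998), relative to all other tested bins. The value was 1.46 at 4C (1.452 to 1.463) and 2.05 at 8C (2.045 to 2.058), and 1.13 in the inputs (1.122 to 1.131). At 16C, where the bins had been chosen for being high, it was 1.88. Single bins followed the sum, with 700 of the 837 above 1 at 2C, 824 at 4C and 833 at 8C. Pericentromeric bins that were not called showed a smaller excess over the uncalled arm bins, of 1.02 at 2C, 1.06 at 4C, 1.19 at 8C and 1.247 at 16C (1.244 to 1.249).

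**Figure D3:**
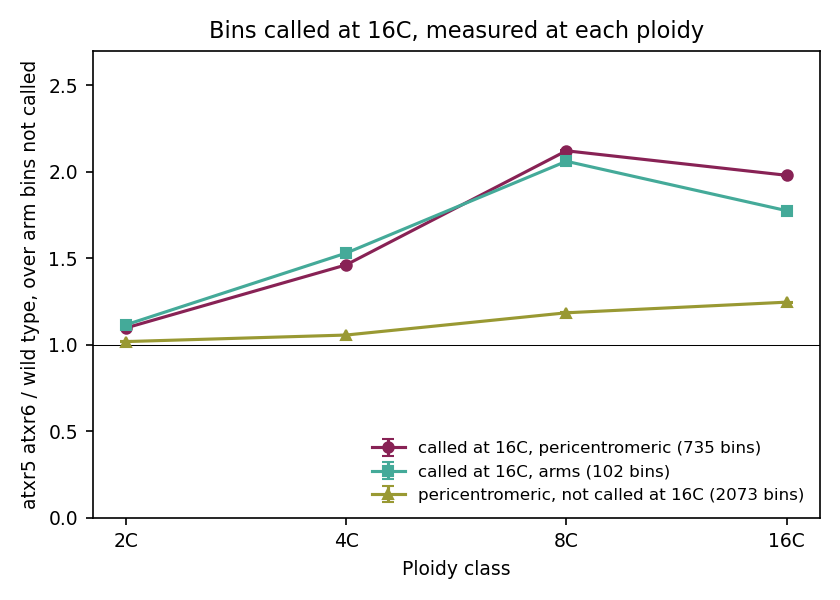
Ratio of atxr5 atxr6 to wild-type reads relative to uncalled arm bins (y axis, linear) at each ploidy class (x axis), for the 735 pericentromeric and 102 arm bins called at 16C and for the 2073 pericentromeric bins that were not called, with exact 95% intervals mostly smaller than the symbols. Called bins reach 2.12 and 2.06 at 8C, whereas uncalled pericentromeric bins reach 1.19 at 8C and 1.247 at 16C.

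Merging called bins gave 328 regions, 248 in the pericentromeres and 80 in the arms. Their median length was 10 kb, 168 were single bins and 18 were 100 kb or longer. The 10 longest all lay in pericentromeres. The longest ran over 260 kb of chromosome 2, from 3220001 to 3480000, with a ratio relative to uncalled arm bins of 1.92 at 16C (1.899 to 1.944), 1.31 at 8C, 1.39 at 4C and 1.07 at 2C. The published genome carries an insertion of mitochondrial DNA in the pericentromere of chromosome 2, and this region was the only one of the 10 with a lower ratio at 8C than at 4C. Next came 220 kb of chromosome 5, from 11040001 to 11260000, with 2.08 at 16C (2.039 to 2.124), 2.37 at 8C, 1.48 at 4C and 1.11 at 2C. On chromosome 1, 180 kb from 15410001 to 15590000 had 1.93 at 16C, 2.20 at 8C and 1.46 at 4C.

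A pair of 170 kb regions followed on chromosome 5. The one from 12110001 to 12280000 had the highest 16C ratio of the 10, 2.09 (2.040 to 2.134), with 2.37 at 8C. The one from 11900001 to 12070000 had 1.77 at 16C and 1.74 at 8C. Chromosome 4 gave 130 kb from 3020001 to 3150000 with 1.90 at 16C, and 120 kb from 4660001 to 4780000 with 1.99. The last 3 regions, each of 120 kb, were chromosome 2 from 5230001 to 5350000 with 2.07, chromosome 3 from 13370001 to 13490000 with 1.96, and chromosome 3 from 13970001 to 14090000 with 1.83. Over the 10 regions the ratio in the inputs was between 1.103 and 1.199.

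H3K27me1 in wild type was highest in the bins that were over-represented in the 16C mutant library. The median of H3K27me1 ChIP over input was 0.910 in uncalled arm bins (quartiles 0.726 and 1.16), 1.88 in uncalled pericentromeric bins (1.05 and 3.504) and 5.84 in called bins (3.56 and 8.22), which are log2 medians of -0.14, 0.91 and 2.55. Called bins of the arms had a median of 2.11 and called pericentromeric bins one of 6.27. Across bins, Spearman's rho between H3K27me1 over input and the 16C mutant over wild-type ratio was 0.566 over 11801 bins, 0.769 over the 2808 pericentromeric bins and 0.319 over the 8993 arm bins. Neighbouring bins are not independent replicates, and these values describe the libraries only.

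In classes of H3K27me1 over input, the 16C ratio went up with the class in arms and in pericentromeres. Pericentromeric bins with H3K27me1 below 1 had a median 16C ratio of 1.09, and 1.12% of them were called. Those at 8 or more had a median of 2.04, and 90.5% were called. In the arms the median 16C ratio was 0.939 below 1, 1.04 between 2 and 4, 1.51 between 4 and 6 in 30 bins, and 2.62 at 8 or more in only 8 bins. The median 8C ratios of the same lowest and highest classes were 1.01 and 2.304 in the pericentromeres and 0.933 and 3.34 in the arms. At 2C the highest classes had medians of 1.08 in the pericentromeres and 1.15 in the arms. The median of mutant H3 ChIP over input also went up with these classes of H3K27me1. Between the lowest and the highest class it went from 0.981 to 3.05 in the pericentromeres and from 0.938 to 5.199 in the arms. The rise of the 16C ratio with the class is therefore not shown to be particular to the methyl mark.

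**Figure D4:**
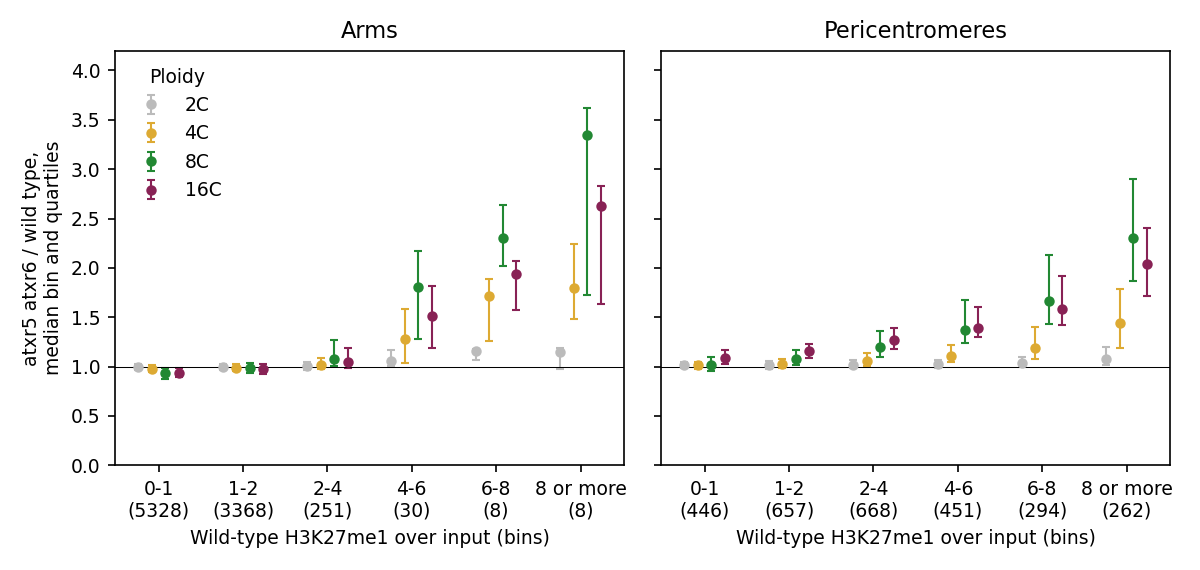
Ratio of atxr5 atxr6 to wild-type reads (y axis, linear, median bin with lower and upper quartile) in classes of wild-type H3K27me1 over input (x axis, number of 10 kb bins in parentheses), for arms and pericentromeres and for each ploidy class. At 16C the median goes from 1.09 to 2.04 in pericentromeres and from 0.939 to 2.62 in arms between the lowest and the highest class.

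H3 ChIP of atxr5 atxr6, set against the mutant input, was also highest in the called bins. Its median was 0.964 in uncalled arm bins, 1.18 in uncalled pericentromeric bins and 2.03 in called bins, and rho with the 16C ratio was 0.475 over all tested bins and 0.693 over pericentromeric bins. An H3 ChIP of wild type and an H3K27me1 ChIP of the mutant were not analysed here, so H3K27me1 per H3 is not given. With 688083 reads, the H3 library had a median of 54 reads per bin, and the H3K27me1 library one of 94.

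Organelle reads were listed in 1 of the 12 files. The 8C mutant library held 11950 plastid reads, 0.0986% of its reads (exact interval 0.0968% to 0.1004%), and 13689 mitochondrial reads, 0.113% (0.111% to 0.115%). The other 11 files listed 0 reads on either organelle genome. Whether organelle reads had been left out of those files was not given in the sources used here, so the zeros describe the files and not the libraries.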

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

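The tests on the spread between libraries, on nuclei of lower ploidy and on carried-over mitochondrial DNA, the check of what the empty windows can show, and every value that leaves out the interval of chromosome 2 or corrects for occupied positions were chosen only after the result was seen. A signal in data outside the comparisons was the organelle reads listed for the 8C mutant library, 13689 mitochondrial and 11950 plastid, where the other 11 files listed 0. Whether organelle reads had been left out of those 11 files was not given in the sources used here, so this is a difference between files and not shown to be one between libraries.

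The first pattern is the pericentromeric excess of atxr5 atxr6 at 4C, 8C and 16C. The largest ratio between any 2 wild-type sorted libraries was 1.02, below the lower limit of the 4C ratio, 1.149. The excess was thus larger than the spread among the wild-type sorted libraries. A difference other than genotype between the wild-type and the mutant set of libraries could not show in wild-type pairs, so it stays open. Correcting for occupied positions took the 16C ratio from 1.42 to 1.44. This value decides nothing on its own, since the correction raises the denser side by construction. At 16C the mutant pericentromeres were the denser side, with 0.0623 starts per mappable position against 0.0389 in wild type. Saturation from starts kept once would by itself lower this ratio and not raise it. A GC effect that differs between libraries was not tested and stays open, as does an effect of the atxr5 atxr6 genotype, with 1 library per class. Extra copies of pericentromeric DNA in endoreduplicated atxr5 atxr6 nuclei are therefore a hypothesis here.

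The second pattern is that the bins called at 16C were further above wild type at 8C (2.05) than at 16C (1.88), although they had been chosen at 16C. Leaving out chromosome 2 from 3.2 to 3.5 Mb gave 2.11 at 8C and 1.88 at 16C, and correction for occupied positions gave 2.11 and 1.92. Both steps could only widen the gap, so neither value is evidence on its own. The interval was itself low at 8C. The called bins were denser in the 8C than in the 16C mutant library, with 0.0925 against 0.0846 starts per mappable position. Reads lost from the interval, or saturation of the denser bins, would thus lower the 8C ratio. The higher 8C value argues against either as its source in these libraries. Nuclei of lower ploidy in the 16C sort would dilute all over-represented bins, but uncalled pericentromeric bins stood higher at 16C (1.247) than at 8C (1.19). This goes against dilution acting alone. Pericentromeric bins with H3K27me1 below 1 also had a higher median at 16C (1.09) than at 8C (1.01). Such a broad shift could hide dilution, so the comparison does not exclude it. A library effect of GC content and a real difference between the classes stay open and were not tested.

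The third pattern is chromosome 2 from 3.2 to 3.5 Mb, where the mutant over wild-type ratio was 1.07 at 2C, 1.36 at 4C, 1.27 at 8C and 1.86 at 16C, against 1.001, 1.18, 1.5004 and 1.504 in the flanks from 2.7 to 3.2 and 3.5 to 4 Mb. A search of the organelle genomes for the 8C mutant library alone stays open: 8.73% of its 100 bp windows held no read start, against up to 8.93% in the other sorted libraries, but an even loss of 31.6% of the reads, the shortfall of the 8C from the 16C ratio, would empty only 0.0812% of the windows, so this measure could not show it. Mitochondrial DNA carried over in different amounts cannot be told apart from a difference in nuclear copies. The interval was 1.94 times as dense, relative to the arms, in the wild-type input as in the highest wild-type sorted library, but mitochondrial reads were listed for 1 library only. No biological explanation was tested for this interval.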

How the results depend on the processing

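The input as reference with each start and strand once, bins of 1 kb with at least 50 reads, the interval of chromosome 2 left out and the correction for occupied positions were chosen after the data were examined. Of 104 alternatives, 48 left the value within its interval, within 1.5 times for a count or an H3K27me1 median, or on the same side of 0.05. A further 54 moved the value further than that, 1 brought it past 0.05 and 1 turned a direction. Of the 48, 15 counted each start and strand once where no repeat was held and could not differ. Others were fixed in advance too. The exact permutation tests with the input pair or without a ploidy class allow no p below 0.0625 and 0.25. A ratio of 2 could add no lower bin to the 0 found at 1.5. The 48 are therefore no measure of robustness. With the input as reference in place of 2C, mutant 4C over input was 0.937, below 1. The mutant input itself stood at 1.16 relative to 2C, above mutant 4C at 1.09. The turn thus came from the change of denominator, and 4C relative to 2C was not altered by it. With each start and strand once, mutant 4C over input was 1.05, so the repeated starts of the input contribute. The same reference gave 1.15 and 1.17 for mutant 8C and 16C (1.29 and 1.31 with each start once), and 0.862, 0.868 and 0.871 for wild-type 4C, 8C and 16C (0.967, 0.974 and 0.978).

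The genotype difference of 0.31 in mean log2 ratio had an exact permutation p of 0.0286 without the ploidy block, the smallest that 70 splits allow. With the input pair it was 0.27 (exact permutation p = 0.0625), and without one ploidy class 0.25 to 0.40 (p = 0.25, the smallest that 8 arrangements allow).

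Mutant over wild-type pericentromeric ratios kept their direction. Limits moved 1 Mb outward gave 1.03, 1.12, 1.34 and 1.36 at 2C, 4C, 8C and 16C and 1.05 in the inputs, and 1 Mb inward 1.04, 1.19, 1.496, 1.491 and 1.08. Leaving out bins with extreme input gave 1.15, 1.42, 1.42 and 1.06 at 4C, 8C, 16C and in the inputs, leaving out the interval of chromosome 2 gave 1.15, 1.41, 1.41 and 1.06, and the correction gave 1.16, 1.43, 1.44 and 1.06. The 8C value exceeded the 16C value inward, without extreme bins and without the interval, so the order of these 2 classes depends on the setting.

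Bins called at 16C numbered 1842 higher and 97 lower at a threshold of 25% above wild type, 265 and 0 at a ratio of 2, 9034 and 2873 in bins of 1 kb with at least 10 wild-type reads (6904 and 2424 with at least 50), and 87 and 0 in bins of 100 kb. A lower ratio admits more bins by construction, and the cause of the counts in 1 kb bins was not tested. Lower bins numbered 7 with at least 1 read. Scaling to total nuclear reads, with a median ratio of 0.928, gave 667 higher and 2 lower (chromosome 1 from 24680001 to 24690000 and chromosome 5 from 21590001 to 21600000). With the mutant 2C library as reference 695 were higher, 659 of them among the 837, and 2 lower (chromosome 3 from 7100001 to 7110000 and from 13540001 to 13550000). Without the interval 812 were higher, and with the correction 876.

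In the libraries that did not choose them, bins called at a ratio of 2 gave 1.18, 1.76, 2.57 and 1.17 at 2C, 4C, 8C and in the inputs. The correction gave 1.1, 1.47, 2.11 and 1.13, leaving out the interval 2.11 at 8C, and each start once 1.13 in the inputs. H3K27me1 medians moved by less than 1.5 times under every alternative run. GC correction, gene lists and transposon classes were not run, as the build is not named. Depth may limit the smallest bins and the H3 ChIP, which had a median of 54 reads per 10 kb bin, but its effect was not tested.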

Other observations

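All comparisons in this part were chosen after the data were examined. The ends of the short arms of chromosomes 2 and 4, next to the nucleolus organizers, lay outside the fixed pericentromeres but carried an excess in atxr5 atxr6. The first 0.1 Mb of chromosome 2 had a mutant over wild-type ratio of 1.01 at 2C (0.981 to 1.047), 1.43 at 4C, 1.98 at 8C (1.916 to 2.037) and 1.81 at 16C (1.758 to 1.870). The first 0.1 Mb of chromosome 4 had 1.05 at 2C, 1.15 at 4C, 1.598 at 8C and 1.57 at 16C. In the inputs chromosome 2 had 1.33, or 1.19 with each start and strand once, and chromosome 4 had 1.097.

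Single arm bins were among those with high ratios, and the highest 16C ratio of a tested bin lay in an arm. That bin, chromosome 2 from 60001 to 70000, stood at 3.26 at 16C, 4.05 at 8C and 2.43 at 4C, with H3K27me1 over input of 12.7 in wild type. Chromosome 5 from 15250001 to 15260000 stood at 2.60 at 16C and 3.40 at 8C, with H3K27me1 of 16.4, and chromosome 1 from 7070001 to 7080000 at 2.31 and 2.98, with 11.9. Chromosome 3 from 10560001 to 10570000 stood at 2.47 and 2.56 with a lower H3K27me1 of 3.94. These bins of chromosomes 5 and 3 lay just outside the fixed pericentromeres, which end at 15 Mb and start at 11 Mb. The last bin of chromosome 3 starts at 23470001 and is incomplete, as the highest read position was 23470770, and it stood at 2.66 at 16C and 3.03 at 8C with 2.48.

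A stretch of 629 bp on chromosome 1, from 11703595 to 11704223, held 0 read starts in all 5 mutant DNA libraries and in the mutant H3 ChIP. The wild-type libraries held 25, 32, 24 and 39 starts there at 2C, 4C, 8C and 16C, 39 in the input and 3 in the H3K27me1 ChIP. The stretch was picked because the mutant DNA libraries lacked it, so its absence there is no check of their labels. It was the only stretch without a start in the mutant DNA libraries that held at least 50 starts in the wild-type ones.

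On chromosome 3, 532 bp from 13748235 to 13748766 showed the opposite. Mutant libraries held 678, 618, 867 and 763 starts at 2C, 4C, 8C and 16C and 237 in the input, which is 10.3, 16.7, 16.6, 14.6 and 7.95 times the density of the arms. Wild-type libraries held 7, 6, 6 and 3 starts and 4 in the input, 0.0646 to 0.152 times that density. The wild-type H3K27me1 ChIP nevertheless held 149 starts there, and the mutant H3 ChIP 198, with each start and strand counted once. That is 37.2 and 69.8 times the density of the arms in these 2 smaller libraries. The files hold no sequences, so it was not tested whether these reads come from chromosome 3 itself or from other DNA that aligns there, such as vector or contaminant sequence. The densities count each start and strand once. With as many as 867 starts in 532 bp, those of the mutant libraries are held down by saturation. They are no copy number of this stretch, and differences between the ploidy classes cannot be read from them.

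The bin of chromosome 3 from 13540001 to 13550000 was picked because it was called lower at 16C than at 2C in both genotypes. Relative to 2C it stood at 0.917 at 4C (0.861 to 0.976), 0.773 at 8C (0.724 to 0.825) and 0.613 at 16C (0.573 to 0.657) in wild type. In the mutant it stood at 0.917 at 4C (0.869 to 0.967), 0.525 at 8C (0.495 to 0.556) and 0.540 at 16C (0.510 to 0.571). Wild-type 4C and 8C and mutant 4C did not pass the 1.5-fold rule.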
